A study of Zea mays with 28 samples.

How the data were processed

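The series holds 28 libraries from developing maize embryos of the inbred line W22, taken 18 days after pollination. They fall into 14 groups of 2 libraries by antibody and genotype. Peak lists of 10 ChIP libraries in 5 groups were analysed: ZmDDM1A, ZmDDM1B and ZmAGO4 ChIP in wild type (WT), ZmDDM1A ChIP in zmddm1a and ZmDDM1B ChIP in zmddm1b. The input, IgG, H3K9me2 and mRNA-seq libraries were not analysed here. The labels number the libraries of a group as replicates and do not say whether they came from separate plants, so the p-values of comparisons between libraries measure the spread between these libraries, which may be technical.

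Per the submitters' processing notes, the tools used in the series were Trim Galore, Bowtie2, Picard, MACS2 2.1.2, TopHat2 2.0.10 and Cufflinks 2.2.1, and the genome build was B73 RefGen_v4. The notes give neither the role nor the order of these tools, and the settings of the peak caller are not given in the sources used here. W22 chromatin was thus placed on the assembly of another inbred line, B73, and sequence that W22 carries and B73 lacks cannot appear in the lists. Each deposited list belongs to 1 library, and no list pooled replicates. The deposited positions of peaks are start and end coordinates, printed here counted from 1. The fold enrichment of a peak is a ratio that the authors deposited for the summit, and it was used only to describe, rank and filter peaks within a list. The deposited p-values and q-values are given as −log10, and the smallest −log10 q of the lists lay between 2.00 and 2.12, which matches a q-value threshold of 0.01. Every listed peak lay on chromosomes 1 to 10.

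The depth of the libraries is not given in the lists and was recovered from them. A fold computed as (pileup + 1) / (background + 1) and a Poisson p-value of the pileup above the background together fix both quantities at a summit. In 7 libraries a whole-number pileup matched 99.998% to 100% of summits within 0.001. In the other 3 (zmddm1a replicate 1 and both zmddm1b libraries) a whole-number pileup matched 0.245%, 8.66% and 0.914%, and the pileup was taken as a scaled value. A scaled pileup has a free fraction, so that it explained 100% of summits is weak evidence for it. For 57.5%, 45.7% and 50.5% of the summits there was 1 solution. The lowest background that recurs in a list is the genome-wide mean coverage, and this floor divided by the smallest peak width, taken as the fragment length, gave the reads per kb. That estimate refers to the smaller of the ChIP and its control when the caller scales to the smaller library, so it is a relative depth. On 20000 simulated summits 100% of unscaled pileups were recovered, and 99.96% of simulated scaled backgrounds with 1 solution (13878 summits) were right within 0.01. Scaled summits with several solutions took the mean of these. Over all 20000 simulated scaled summits, 96.35% of backgrounds were right within 10%.

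A region of a group is a merged stretch of peaks that holds at least 1 peak of each replicate. Regions overlapped when they shared at least 1 bp. Observed overlaps were compared with 1000 circular shifts of the second set along each chromosome (200 for alternatives, 50 for reciprocal overlap), and with local shifts of 10 to 50 kb, which keep the regional density. The p-values of shifts are one-sided permutation values, and the smallest that 1000 shifts can give is 0.000999. For regions called for all 3 proteins no p is given, since shifting the sets independently of each other also removes the overlap of each pair. The largest end in any list served as the chromosome length. Peak numbers were compared by exact permutation of 2 against 2 libraries, two-sided, which cannot give a p below 0.333, and the shares along chromosomes by an exact sign-flip test over 10 chromosomes, which cannot give a p below 0.00195. Intervals of shares of regions are exact Clopper-Pearson 95% intervals and cover counting error only, and neighbouring regions are not independent. In a test on simulated data, 37060 simulated ZmDDM1A regions placed at random overlapped the ZmDDM1B regions in 2.29% of cases, 0.976 times the share of shifted ones. With 30% of them placed on ZmDDM1B regions and the rest at random, 31.5% overlapped.

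The tests, the alternatives and the rule for regions named in the text were fixed before the data were examined, except where stated. The rule took the 5 regions of each WT antibody without any mutant peak and with the highest value of the smaller of the 2 replicate folds, the 5 regions called in all 6 WT libraries with the highest smallest fold, and the 5 regions per mutant called in both of its libraries with the highest smaller fold. Regions named in observations follow the same rule. Alternatives were a stricter threshold (−log10 q of at least 5), a fold of at least 4, other overlap rules (50% covered or 50% reciprocal), the union of replicates, each replicate left out, lists of equal length and regions with a mutant peak removed. The depth-matched peak numbers, the removal of peaks with high background and some of the counts without a replicate were added after the data were seen. The summit distances, the shares of mutant regions along chromosomes with their p-values, and the shares called in the mutants by WT fold were not in the plan either. The shares near promoters and the gene lists that were planned needed a gene annotation of B73 RefGen_v4. The gene table at hand is of Zm-B73-REFERENCE-NAM-5.0, so no coordinate of it was used and regions are given by position only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.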

Results

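Chromatin immunoprecipitation was read out in 18-day embryos of maize with antibodies against 3 proteins. ZmDDM1A and ZmDDM1B are maize homologues of DDM1, a SNF2-type chromatin remodeller needed for DNA methylation in plants. ZmAGO4 is an Argonaute protein of the pathway in which small RNAs direct DNA methylation. Each antibody was used on WT embryos in 2 libraries, and the 2 DDM1 antibodies were also used on embryos labelled as mutants of their own antigen, in 2 libraries each. The title of the series places DDM1 and this methylation pathway together on active chromatin, so the comparisons below ask where the 3 proteins were called and whether they were called at the same places. Coordinates are of B73 RefGen_v4, and the genes at these positions were not analysed here.

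The ZmAGO4 lists were the longest, with 99625 peaks in replicate 1 and 98086 in replicate 2, covering 110 and 107 Mb. ZmDDM1A had 45957 and 45011 peaks over 21.5 and 22.0 Mb, and ZmDDM1B had 56570 and 53298 peaks over 25.9 and 25.7 Mb. ZmAGO4 peaks were wider, with median widths of 833 and 829 bp, against 390 and 412 bp for ZmDDM1A and 381 and 403 bp for ZmDDM1B. The median fold enrichment given by the authors was 6.20 and 6.43 for ZmAGO4, 3.98 and 3.93 for ZmDDM1A, and 4.35 and 4.36 for ZmDDM1B. The depth recovered from the lists was 31.4 and 28.5 reads per kb for ZmAGO4, 17.9 and 17.8 for ZmDDM1A, and 13.8 and 12.7 for ZmDDM1B, and since it differed between antibodies the lengths of their lists are not compared further. The replicates of a WT group shared on average 93.6% of their peaks for ZmAGO4, 83.0% for ZmDDM1A and 79.0% for ZmDDM1B. This left 89782 ZmAGO4 regions, 37060 ZmDDM1A regions and 42450 ZmDDM1B regions called in both replicates.

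The mutants give the background of each DDM1 antibody when its antigen's gene is mutated. With the ZmDDM1A antibody, 817 and 883 peaks were called in zmddm1a, a mean of 850 ± 46.7 (SD, n = 2) against 45484 ± 669 (SD, n = 2) in WT, which is 53.5-fold fewer. With the ZmDDM1B antibody, 1870 and 766 peaks were called in zmddm1b, a mean of 1318 ± 781 (SD, n = 2) against 54934 ± 2314 (SD, n = 2) in WT, which is 41.7-fold fewer. Every WT library exceeded every mutant library of its antibody, by at least 51.0-fold for ZmDDM1A and 28.5-fold for ZmDDM1B. The exact permutation test gave p = 0.333 for each antibody (n = 2 against 2, two-sided), the smallest value this design allows. The depth recovered from the lists was lower in the mutants, at 11.02 and 8.60 reads per kb in zmddm1a and 9.92 and 10.8 in zmddm1b. This is 0.550 and 0.781 times the WT value. The pileup was taken as scaled in zmddm1a replicate 1 and both zmddm1b libraries, so there the ChIP may be deeper than this estimate. The mean log2 losses of the antibodies differed by −0.22 (ZmDDM1A minus ZmDDM1B), and the sign turned without zmddm1b replicate 1 (0.42). The planned exact permutation of the genotype labels (p = 1 over 36 assignments) could not pass 0.05, and it says nothing on whether the losses differ.

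**Figure D1:**
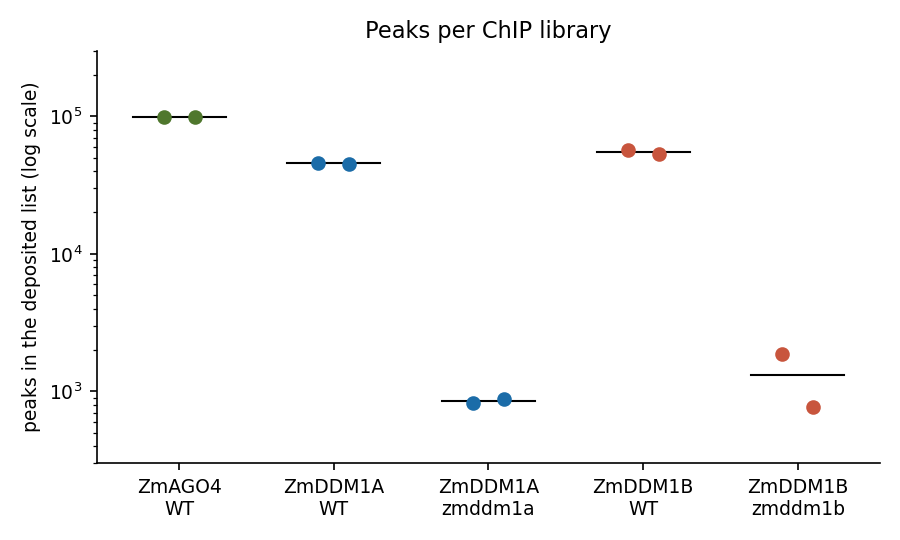
Peaks in each deposited list on a log scale, by antibody and genotype. Points are libraries and black lines are means of 2 libraries. The 4 mutant libraries lie between 766 and 1870 peaks, and the 4 WT libraries of the same antibodies between 45011 and 56570.

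Few WT regions were called in the mutants. In zmddm1a a peak of either library met 1179 of the 37060 ZmDDM1A regions, or 3.18% (95% interval 3.00 to 3.37), and in zmddm1b 1170 of the 42450 ZmDDM1B regions, or 2.76% (2.60 to 2.92). These shares were still 51.9 and 26.6 times those after shifting the mutant peaks along the chromosomes (permutation p = 0.000999 for both, the smallest that 1000 shifts give). The peaks that the mutants kept were mostly places called in WT for the ZmDDM1A antibody: of 352 regions called in both zmddm1a libraries, 348 overlapped a WT ZmDDM1A region, while of 236 regions called in both zmddm1b libraries 131 overlapped a WT ZmDDM1B region. The zmddm1a share was 1.98% without replicate 1 and 2.14% without replicate 2. The zmddm1b share rested mainly on replicate 1, since without it 0.473% of the ZmDDM1B regions were met, 15.1-fold over shifts, against 2.59% (32.0-fold) without replicate 2. Counting only WT regions covered to 50% by mutant peaks lowered the shares to 1.48% and 1.29%, and counting only mutant regions called in both libraries lowered them to 0.934% and 0.309%. The zmddm1a replicates shared 41.5% of their peaks on average and the zmddm1b replicates 21.7%.

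Among the WT regions that no mutant list called, the 5 with the highest fold are given for each antibody. ZmDDM1A regions that zmddm1a also called reached higher WT folds, up to 54.2 and 52.3. For ZmDDM1A the first without a mutant peak was on chromosome 6 at 159037019 to 159037415, with folds of 31.7 and 31.7, and it was in no ZmDDM1B or ZmAGO4 list. The second, on chromosome 9 at 116367851 to 116368209, had folds of 32.6 and 26.9, no ZmDDM1B peak, and ZmAGO4 folds of 5.16 and 5.17. The other 3, on chromosome 9 at 120308130 to 120308880, chromosome 2 at 56545263 to 56545608 and chromosome 3 at 206109576 to 206110232, were called in all 6 WT libraries. For ZmDDM1B all 5 were called in all 6 WT libraries. They lay on chromosome 3 at 12871812 to 12872233 (ZmDDM1B folds 19.9 and 19.1), chromosome 2 at 37572710 to 37573775, chromosome 9 at 122112412 to 122113755 and at 141495316 to 141495990, and chromosome 1 at 45513269 to 45513624. For ZmAGO4 the highest was on chromosome 4 at 195519607 to 195520098, with folds of 36.4 and 33.7, and the next on chromosome 2 at 47668376 to 47669431, with folds of 35.1 and 33.2. Of the 5 strongest ZmAGO4 regions none was called in all 6 WT libraries, and the 1 on chromosome 3 at 16793994 to 16794573 was in no DDM1 list.

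ZmDDM1A and ZmDDM1B were called at largely the same places. Of the ZmDDM1A regions 83.2% overlapped a ZmDDM1B region, against 2.36% after shifts, a 35.3-fold excess (permutation p = 0.000999, the smallest possible). Of the ZmDDM1B regions 72.7% overlapped a ZmDDM1A region, a 35.2-fold excess with the same p. Between single libraries the first share was 80.3% ± 0.938 (SD over the 4 pairs of libraries) and the second 66.4% ± 1.55. Summits were close: where peaks of the same replicate number overlapped, their summits lay a median of 54 bp apart in replicate 1 and 56 bp in replicate 2. Of all ZmDDM1A summits 71.0% in each replicate had a ZmDDM1B summit within 200 bp, against 1.54% and 1.36% after shifts.

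In the full lists, most DDM1 regions were also ZmAGO4 regions, and most ZmAGO4 regions were not DDM1 regions. Of the ZmDDM1A regions 83.4% overlapped a ZmAGO4 region (10.8-fold over shifts), and of the ZmDDM1B regions 80.4% (10.4-fold). In the other direction 30.8% of the ZmAGO4 regions overlapped a ZmDDM1A region and 33.7% a ZmDDM1B region (10.3-fold and 9.89-fold). All 4 had a permutation p = 0.000999, the smallest possible. Summits of overlapping peaks were farther apart than between the DDM1 proteins, with medians of 261 and 270 bp for ZmDDM1A and ZmAGO4 and 299 and 300 bp for ZmDDM1B and ZmAGO4. ZmAGO4 peaks were also wider, which leaves room for more distant summits. A ZmAGO4 summit lay within 200 bp of 35.0% and 33.6% of all ZmDDM1A summits and of 27.5% and 27.2% of all ZmDDM1B summits. After shifts these shares were 2.19% to 2.28%. With lists of equal length, made of the strongest regions of each set, the shares were 53.7% of ZmDDM1A and 56.5% of ZmDDM1B regions in ZmAGO4 regions, and 45.3% and 47.5% in the other direction. With at least 50% of the DDM1 region covered by ZmAGO4 regions, the shares were 80.8% of ZmDDM1A and 74.8% of ZmDDM1B regions (15.1-fold and 13.9-fold over shifts). Under a 50% reciprocal overlap the shares fell to 24.5% of ZmDDM1A and 19.98% of ZmDDM1B regions, which was still 20.4-fold and 16.5-fold over shifts. ZmAGO4 regions had a median width of 988 bp against 511 and 509 bp, so rules that require 50% of the ZmAGO4 region are harder to meet. Of the ZmAGO4 regions 11.5% and 11.3% were covered to 50% by ZmDDM1A and ZmDDM1B regions, and with a fold of at least 4 in both sets 14.2% and 20.7% overlapped one.

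**Figure D2:**
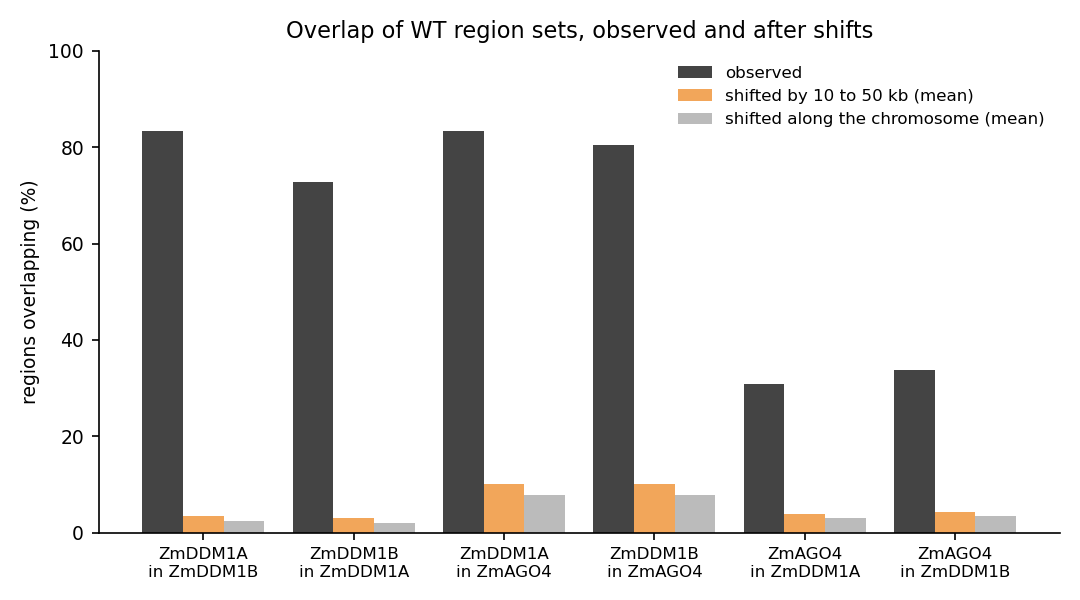
Percent of the regions of the first WT set that overlap the second by at least 1 bp (dark bars), with the mean after local shifts of 10 to 50 kb (orange) and after shifts along the whole chromosome (grey). The observed shares run from 30.8% to 83.4%, and the largest mean after local shifts is 10.1%.

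Regions called for all 3 proteins were the largest class of DDM1 regions. They made up 26416 of the ZmDDM1A regions (71.3%) and 26702 of the ZmDDM1B regions (62.9%), and 24043 of the ZmAGO4 regions (26.8%). Only 4.64% of the ZmDDM1A regions and 9.79% of the ZmDDM1B regions overlapped neither other set, while 62.3% of the ZmAGO4 regions overlapped no DDM1 region. The ZmAGO4 share fell to 8.63% when 50% of the region had to be covered, while the ZmDDM1A and ZmDDM1B shares were 67.5% and 57.2%. Merging the peaks of all WT libraries gave 24115 regions with a peak of each of the 6 libraries, of which 22470 held no mutant peak. The strongest of these by their smallest fold lay on chromosome 2 at 192210553 to 192214511 (folds of 9.69 to 13.6 over the 6 libraries), chromosome 9 at 128999784 to 129001401, chromosome 6 at 157513713 to 157515837, chromosome 2 at 189672348 to 189673525 and chromosome 10 at 143309815 to 143311239. Of these 5, the region on chromosome 9 was also called in both zmddm1a libraries and that on chromosome 6 in both zmddm1b libraries.

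Within each library, regions shared with another antibody had a higher median fold than unshared ones. The log2 difference was 0.24 ± 0.0016 (SD, n = 2) for ZmDDM1A, 0.37 ± 0.022 for ZmDDM1B and 0.61 ± 0.0076 for ZmAGO4. Shared ZmAGO4 regions were also wider, with a median of 1373 bp against 811 bp, and among regions of intermediate width the ZmAGO4 difference was 0.14. With 50% coverage as the rule for sharing it turned to −0.59, and the 12720 ZmAGO4 regions that met this rule had a median width of 739 bp against 1036 bp for the others. No p-value is given, since regions of 1 library are not replicates.

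All 3 proteins were called more often towards the chromosome ends. The first and last 20% of the chromosomes, 40% of their length, held 55.4% of the ZmDDM1A regions, 55.6% of the ZmDDM1B regions and 51.7% of the ZmAGO4 regions. Each set exceeded 40% on all 10 chromosomes (exact sign-flip p = 0.00195, two-sided, the smallest possible). The share was lowest on chromosome 4 for ZmDDM1A and ZmDDM1B (44.2% and 43.9%) and on chromosome 6 for ZmAGO4 (46.4%). The middle 20% of the chromosomes held 11.9%, 11.7% and 13.7% of the regions of the 3 sets, where a uniform spread would put 20%. The regions called in both mutant libraries lay towards the ends too: the outer 40% held 56.8% of those of zmddm1a (above 40% on 9 of 10 chromosomes, exact sign-flip p = 0.00391) and 55.9% of those of zmddm1b (9 of 10, p = 0.0117). In single zmddm1b libraries the shares were 52.7% and 46.6%. The sign-flip test compares with chromosome length and not with the sequence where peaks can be called, which was not measured. It therefore cannot tell the location of the proteins from that of such sequence.

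**Figure D3:**
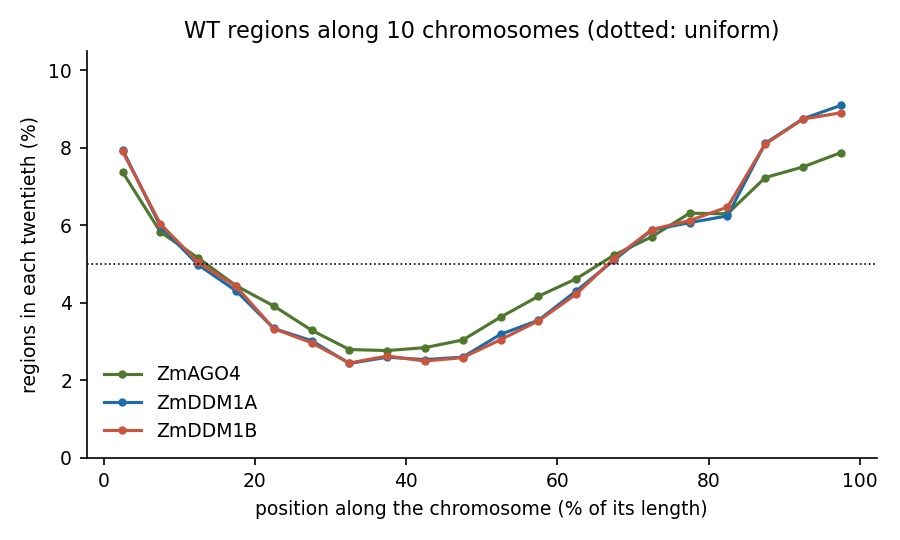
Percent of the WT regions of each protein in 20 equal parts of the chromosome length, averaged over the regions of all 10 chromosomes. The dotted line is the 5% of a uniform spread. The last part holds 9.09% of the ZmDDM1A, 8.90% of the ZmDDM1B and 7.87% of the ZmAGO4 regions.

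The share of WT regions called in the mutants changed with their strength. The WT regions of each antibody were placed in 10 equal groups by the smaller of the 2 replicate folds. In the group with the highest fold 14.6% of the ZmDDM1A regions met a zmddm1a peak and 10.98% of the ZmDDM1B regions met a zmddm1b peak, and in group 2 the shares were 0.594% and 0.801%. The weakest ZmDDM1A group stood above group 2, at 3.21%.

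**Figure D4:**
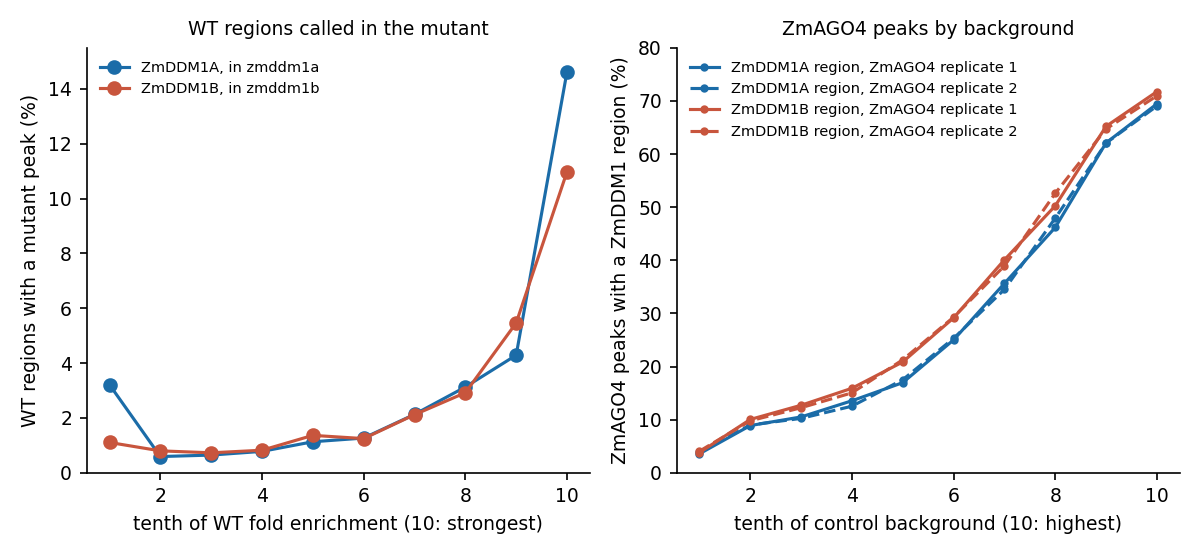
Left, percent of WT ZmDDM1A and ZmDDM1B regions that meet a peak of the mutant, in 10 equal groups by WT fold, which reaches 14.6% and 10.98% in the strongest group. Right, percent of ZmAGO4 peaks of each replicate that overlap a ZmDDM1A or ZmDDM1B region, in 10 equal groups by the control background recovered at the summit, which rises from 3.58% to 69.4% for ZmDDM1A in replicate 1.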

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

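Over 26 results, 192 alternatives were run: 161 kept the direction and the side of the threshold or moved by less than the spread, 29 moved by more and 2 reversed. The 161 do not measure robustness. Overlaps tested by shifts were counted by the side of p, whatever the share. At a fold of at least 4, ZmDDM1B regions in ZmDDM1A regions fell from 72.7% to 50.6%. Under 50% reciprocal overlap, ZmDDM1A regions in ZmAGO4 regions fell from 83.4% to 24.5%. Both count among the 161. The tests of peak numbers and of the difference in loss could not pass the threshold. Depth-matched peak numbers, removal of high-background peaks and the counts without a replicate for regions of all 3 antibodies, fold differences and peaks of both mutants were chosen after seeing the data. The 2 reversals were the difference in loss between the antibodies, which ran from −0.87 to 0.42 when 1 library was left out (0.42 without zmddm1b replicate 1), and the fold difference at shared ZmAGO4 regions, which was −0.59 with 50% coverage, a rule that selects narrower regions. The causes of the moves below were not tested. Replicate overlap was 74.1%, 70.8% and 87.6% for WT ZmDDM1A, ZmDDM1B and ZmAGO4 under 50% reciprocal overlap, and 82.2% for WT ZmDDM1A and 48.1% for zmddm1a at −log10 q of at least 5. The shares of ZmDDM1A, ZmDDM1B and ZmAGO4 regions called for all 3 antibodies were 67.5%, 57.2% and 8.63% with 50% coverage, 70.1%, 60.7% and 23.8% at the stricter q, and 69.7%, 60.9% and 25.4% without regions holding a mutant peak. From the union of replicates they were 57.4% for ZmDDM1B and 32.7% for ZmAGO4. Leaving out a replicate gave 63.0% to 63.9%, 50.6% to 52.8% and 25.3% to 25.3%. The log2 differences at shared ZmDDM1A, ZmDDM1B and ZmAGO4 regions were 0.63, 1.07 and 1.62 for −log10 q in place of fold, and 0.33, 0.41 and 0.14 among regions of intermediate width. That of ZmDDM1A was 0.27 with 50% coverage.

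Between WT libraries of different antibodies the replicate numbers gave no sign of a pairing: overlaps between same-numbered and differently numbered libraries differed by at most 0.0874 percentage points. WT and mutant libraries were not compared in this way. With the replicate block the log2 losses were −5.74 for ZmDDM1A and −5.52 for ZmDDM1B (exact sign-flip p = 0.5, n = 2, the smallest possible). The overlap of ZmDDM1A with ZmDDM1B was then 80.3% and with ZmAGO4 81.8%. No call changed, but for the losses none could, since this p cannot fall below 0.5. Promoter shares and gene lists were not run, since no annotation of the build of the lists was used here, and the restriction to chromosomes 1 to 10 moved nothing because every listed peak lies there. Peaks shared by both mutants rest on 6 regions. Depth may limit the mutant lists in part. At the depth recovered from those lists, the WT libraries would have kept 33751 of 45484 ZmDDM1A and 50054 of 54934 ZmDDM1B peaks on average.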

Other observations

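The tests on the strongest ZmDDM1A regions, the comparisons by background and by the other DDM1 protein and the removal of high-background peaks were chosen after the results were seen. The tests of depth, local shifts and antibody cross-binding were set before their results were seen.

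The ZmAGO4 peaks that carried a DDM1 region differed from the rest in the coverage at their summits, in the control and in the immunoprecipitate. ZmAGO4 peaks of each replicate were placed in 10 equal groups by the background recovered at the summit, relative to the genome-wide floor. In replicate 1 the share with a ZmDDM1A region rose over these groups from 3.58% to 69.4%, and the share with a ZmDDM1B region from 3.80% to 71.7%. In replicate 2 the shares rose from 3.91% to 69.0% and from 4.07% to 71.0%. By fold in place of background the relation was not monotone: the share with a ZmDDM1A region was 31.4% among the weakest ZmAGO4 peaks of replicate 1, 17.8% in group 4 and 48.7% among the strongest. At each of 20 levels of fold and replicate, the fifth of peaks with the highest background held more ZmDDM1A regions (47.9% to 89.7%) than the fifth with the lowest (0.754% to 13.5%), and the same was so for ZmDDM1B. By the pileup of the immunoprecipitate the shares also rose, from 4.20% to 75.6% for ZmDDM1A and from 5.69% to 81.6% for ZmDDM1B in replicate 1. At a given fold background and pileup rise together, so the relation cannot be assigned to the control. DDM1 summits themselves lay at a higher background than ZmAGO4 summits, with medians of 3.01 and 2.92 times the floor for ZmDDM1A, 3.42 and 3.05 for ZmDDM1B, and 2.15 and 2.12 for ZmAGO4. The recovered depth differed between the antibodies, and its effect on these medians was not tested.

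ZmAGO4 was called more often at ZmDDM1 peaks where the other DDM1 protein was also called. Of the ZmDDM1A peaks with a ZmDDM1B region 86.9% and 85.2% (replicates 1 and 2) met a ZmAGO4 region, against 68.2% and 69.7% of those without. For ZmDDM1B peaks the shares were 87.9% and 86.3% with a ZmDDM1A region and 54.7% and 53.6% without. Compared within 10 levels of fold, the differences were 16.0 and 14.6 percentage points for ZmDDM1A and 29.9 and 30.4 for ZmDDM1B. Both mutants shared 6 of the regions called in both of their libraries, 1.70% of those of zmddm1a and 194-fold over shifts (permutation p = 0.000999, the smallest possible). The share was 1.59% (215-fold) and 0.857% (156-fold) without zmddm1a replicate 1 or 2, 1.99% (77.8-fold) and 5.68% (81.6-fold) without zmddm1b replicate 1 or 2, and 7.86% (110-fold) for the union of replicates. Peaks of the other mutant, zmddm1b, met 2.58% of the WT ZmDDM1A regions, against 3.18% for zmddm1a, and 9.33% of the 1179 ZmDDM1A regions called in zmddm1a. In zmddm1a replicate 2, 239 of 883 summits (27.1%) had a background over 10 times the floor, against 2.20% in replicate 1. Without such peaks the losses were 62.3-fold for ZmDDM1A and 43.3-fold for ZmDDM1B.

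The first pattern is the loss of peaks in the mutants. A lower depth was tested by thinning the recovered pileups and backgrounds of the WT summits to the depth recovered from the mutant lists. The thinned summits were held to the smallest −log10 p of the stricter of the 2 mutant lists, 5.60 for ZmDDM1A and 5.16 for ZmDDM1B. This left 33751 ZmDDM1A and 50054 ZmDDM1B peaks on average, 39.7 and 38.0 times the mutant means, where depth as the cause required at most 1.5 times. Loss of the antigen, which the genotypes name, remains a hypothesis. A less efficient immunoprecipitation is not excluded. While zmddm1a still called 95 of the 100 strongest ZmDDM1A regions, this holds for the strongest regions alone. In zmddm1b only 23 and 4 of the 100 strongest ZmDDM1B regions were called.

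The second pattern is the overlap of the WT sets. Binding in the same broad parts of the chromosomes is argued against by local shifts of 10 to 50 kb, over which the overlap of ZmDDM1A was 24.0-fold with ZmDDM1B and 8.27-fold with ZmAGO4. The shifts do not hold regions to sequence where peaks can be called. Sharing of such sequence, or of high coverage, at a finer scale was therefore not tested and may add to these folds. If the ZmDDM1A antibody also bound ZmDDM1B, regions shared by both should stay in zmddm1a, yet of those callable at the mutant depth 5.13% were called there, and 3.33% in zmddm1b in the reverse test. Likewise 5.58% of the callable ZmDDM1A regions in ZmAGO4 regions were called in zmddm1a, the share that enrichment without the antigen could account for. The 5.13% and 3.33% argue against cross-binding only if the other DDM1 protein stays bound in each mutant, which was not measured. They also need an immunoprecipitation that works in the mutants as well as in WT. The 5.58% argues against antigen-free enrichment, as the main cause, under this second condition alone. For that condition there are only the strongest regions, as above. The ZmAGO4 antibody has no mutant among the analysed libraries, so its own specificity stays open.

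The third pattern is that the strongest ZmDDM1A regions were called in zmddm1a too: 95 of the 100 with the highest smaller fold (95% interval 88.7% to 98.4%), while of the 100 strongest ZmDDM1B regions zmddm1b replicate 1 called 23 (15.2% to 32.5%) and replicate 2 called 4. Places enriched in any immunoprecipitate are argued against, as the whole cause, by the 4.21% of the 95 called with the ZmDDM1B antibody in zmddm1b, whose replicates overlapped poorly (21.7%). The 29 of the 95 without a ZmDDM1B peak in either WT library also argue against it. The overlaps of the mutants above leave room for a part. The 83.2% of the 95 in ZmAGO4 regions does not decide this, being near the 83.4% of all ZmDDM1A regions and below the 90% of the strongest 1000. Binding of the ZmDDM1A antibody to ZmDDM1B at all of the 95 is argued against by the same 29, or 30.5%, and among the strongest 1000 the regions called in zmddm1a were less often ZmDDM1B regions (74.8%) than the others (91.8%). For the 63.2% of the 95 that were ZmDDM1B regions, against 83.2% of all ZmDDM1A regions, such binding cannot be told apart from other causes, because both proteins were called there. Repeats collapsed in the assembly stay open too, since 0% of the 95 had a summit background over 10 times the floor but 0 of the 1011 WT summits with such a background reached the folds of the strongest 100, and binding to a further protein was not tested.

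The regions called in both zmddm1a libraries with the highest fold were on chromosome 7 at 157971355 to 157971792 (zmddm1a folds 46.2 and 55.6, WT folds 54.2 and 52.3) and chromosome 1 at 296360666 to 296361536 (38.0 and 45.0, WT 48.3 and 39.3), neither with a ZmDDM1B peak in WT. The other 3, on chromosome 2 at 200785846 to 200787030, chromosome 6 at 168949837 to 168951791 and chromosome 2 at 12050179 to 12050609, had ZmDDM1B folds in WT of 4.67 to 9.27. In zmddm1b the highest were on chromosome 7 at 84206696 to 84207066 (15.0 and 13.2) and chromosome 5 at 221648971 to 221649738 (11.9 and 13.0). The latter was also called in both zmddm1a libraries (3.73 and 3.72), with WT folds of 44.4 and 28.5 for ZmDDM1A and 13.6 and 23.5 for ZmDDM1B.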
